A study of Mus musculus with 12 samples.

How the data were processed

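Polyadenylated RNA was sequenced from 1000 sorted bone-marrow cells per mouse, taken as lineage-negative, KIT-positive, SCA1-positive, FLT3-negative and CD48-negative, a gate that holds hematopoietic stem cells. Per the labels, the cDNA was made with a SMART-Seq v4 kit and the mice were naive wild-type C57BL/6 animals or Osmr knock-out animals. The labels list 12 samples, and the tables hold 11 of them, 6 wild type and 5 knock-out, each from a different mouse. The knock-out sample numbered 4 has no column in the tables and was not analysed here.

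Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36.6, checked with FastQC 0.72, aligned to the mm10 genome build with HISAT2 2.1.0, counted per gene with HTSeq 0.9.1 and compared with the DESeq2 wrapper 2.11.40.6. The gene annotation and the strand setting of the counting are not given in the sources used here. The authors divided each library's gene counts by its DESeq2 size factor, so the deposited expression signal is a normalised read count. The authors also made log2 scale values with DESeq2's regularised logarithm and its variance stabilising transformation. A deposited table without column names holds the authors' DESeq2 comparison. Tests on its values showed that it gives the mean normalised signal, the log2 fold change, its standard error, the Wald score, the p-value and the adjusted p-value of each gene, as deposited. All 615 genes at an adjusted p under 0.05 in the authors' table have the sign of the wild-type mean minus the knock-out mean, so the fold changes from that table are printed here with their sign turned, as knock-out over wild type.

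Each library's deposited values were whole multiples of 1 step, and dividing by that step gave back whole read counts, with a largest distance from a whole number of 1.4e-09. Library totals ran from 9.50 to 22.1 M reads (M for the SI prefix mega) per library. DESeq2 size factors computed anew from these reads differed from the authors' by at most 3.66e-15. The floor for a group or library without reads was set at 3 reads. Intervals and floors cover counting error only, because PCR reads without molecular identifiers are not independent molecules.

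The main comparison was fixed before the data were examined. It used log2(normalised count + 1) for the 13358 of 43279 genes with a normalised count of at least 10 in at least 5 libraries. The model held genotype alone and was fitted with limma 3.58.1 (lmFit, then eBayes with a mean-variance trend) in R 4.3.3, and two-sided p-values were adjusted by Benjamini-Hochberg with 0.05 as the threshold. All adjusted p-values in the text come from limma unless another tool is named. Also fixed before the data were examined were 40 gene lists, which covered pathways, cell cycle phases, markers of other cells, genes flanking Osmr and markers of substrain differences. Of their 1237 genes, 1207 were found in the table by symbol and 1003 were tested. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 40 lists, and again with an estimated correlation. Single quantities, Osmr included, were compared by exact two-sided permutation over all 462 splits of the libraries, whose smallest possible p is 0.0022. Gene positions, lengths and GC contents came from GENCODE M21 on GRCm38, which is the mm10 assembly, and 39458 of the 43279 symbols had a position there.

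The genes named were chosen by a rule fixed before the data were examined. It takes Osmr; in each direction the genes past the threshold with a mean normalised count of at least 50, filled to 5 by lowest p where fewer pass; up to 4 members of each list past the list test or with a member past the threshold; the 3 members of lowest p from 7 lists; and the 5 genes of lowest adjusted p in each direction in the authors' table. The 7 lists are those of the OSM and JAK-STAT pathway, long-term stem cell identity, quiescence, S phase, G2/M phase, adhesion and homing, and Osmr flanking genes. This gave 64 genes, of which 63 were tested, and 2 are not reported here. Other genes are named as chosen after their values were seen.

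The alternatives were pseudocounts of 0.5 and 10, no filter and a filter at 50, TMM and quantile scaling, the authors' log2 values, array weights, no trend, robust variance estimates, 1 surrogate variable (sva 3.50.0), edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, label number as a replicate block, and leaving out each library. Added after the data were seen were DESeq2 with a beta prior, a length and GC correction, the model without wild type 1 and knock-out 3, exact tests of list means, and a covariate for the label numbers. That covariate sets libraries numbered 1 to 3 against those numbered 4 to 6, with 3 wild-type and 3 knock-out libraries in the lower set and 3 and 2 in the upper set. The labels give no batch, so these sets were defined from the data. Label numbers were also tested for pairing between genotypes: the correlation of same-number libraries, as deviations from their genotype means, ran from 0.0203 to 0.0986 over 5 numbers, and the numbers were not treated as pairs.

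The tests were tried on simulated data of the same size, with 100 genes changed 2-fold and 100 changed 4-fold among 13358. At the 0.05 threshold limma recovered 6% of the 2-fold and 40% of the 4-fold changes, with 4 false calls among 50. For edgeR these values were 3%, 41% and 3 among 47, and for DESeq2 they were 15%, 59% and 24 among 98. For DESeq2 with a beta prior they were 14%, 58% and 23 among 95. These simulated data held no difference between label numbers 1 to 3 and 4 to 6. Their variances came from the real libraries with genotype alone in the model, so the real difference between the number sets entered as noise. Genes were drawn independently, so these values describe the simulated settings only. With a difference between the number sets added on top, limma with genotype alone recovered 3% and 18%, with 0 false calls among 21. With the number sets as a covariate it recovered 5% and 46%, with 3 false calls among 54.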

Results

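The data set holds 11 RNA-seq libraries of sorted bone-marrow stem and progenitor cells, 6 from wild-type mice and 5 from mice without Osmr, with 1 library per mouse. Osmr encodes the receptor chain through which oncostatin M signals together with gp130, and the series asks how loss of this signal in the bone-marrow niche alters hematopoietic stem cells. Library totals were 22.1 M reads in wild type 1 and between 9.89 and 13.6 M reads in wild type 2 to 6. The knock-out libraries held between 9.50 and 11.2 M reads. The means were 13.5 ± 4.45 M reads in wild type (SD, n = 6) and 10.6 ± 0.693 M reads in the knock-out (SD, n = 5), with an exact permutation p of 0.119.

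The libraries separated by more than genotype. The first principal component held 21.2% of the variance and placed the knock-out libraries between 18.96 and 100.9, wild type 6 at 13.5 and the other wild types between -138 and -18.0. The second held 16.5% and separated libraries numbered 1 to 3, at 16.0 to 84.0, from those numbered 4 to 6, at -62.6 to -39.5, in both genotypes. The nuclear RNA Malat1 had a mean normalised count of 59217 ± 34957 in the lower numbers (SD, n = 6) and 186746 ± 41534 in the upper (SD, n = 5). With genotype in the model, limma placed 348 genes higher and 626 lower in numbers 4 to 6. Values within each number set are therefore given for Osmr, for the 3 genes past the threshold and for the 7 lists past the list test.

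**Figure D1:**
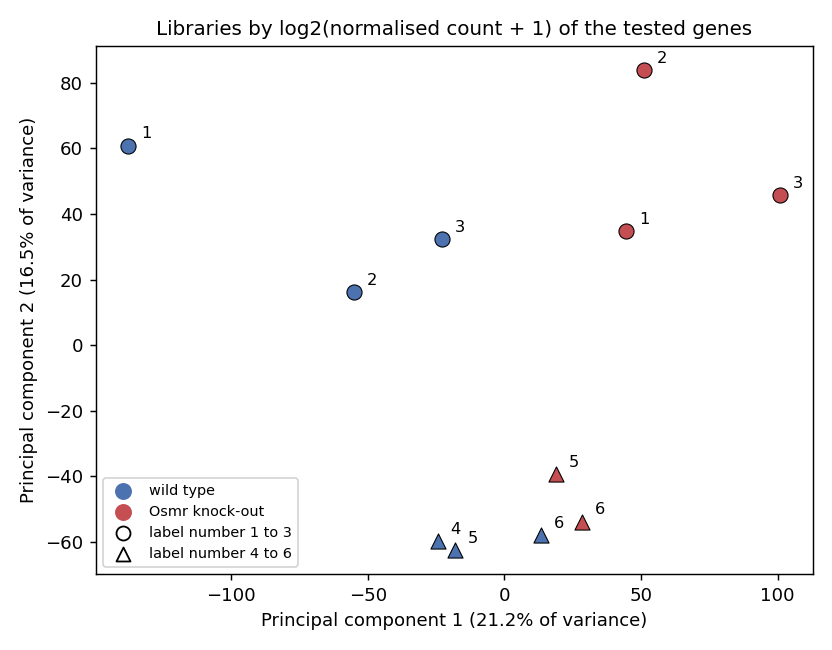
Principal components 1 and 2 of log2(normalised count + 1) over the tested genes, 1 point per library, with colour for genotype and shape for label number. Knock-out libraries lie at 18.96 or more on component 1, and libraries numbered 4 to 6 lie at -39.5 or less on component 2 in both genotypes.

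Osmr itself was close to absent from these cells in both genotypes. Its reads totalled 13 over the 6 wild-type libraries and 4 over the 5 knock-out libraries. The normalised count was 1.60 ± 2.64 in wild type (SD, n = 6) and 0.875 ± 0.856 in the knock-out (SD, n = 5), with an exact permutation p of 0.848. A count of 0 allows 3 reads, which is between 1.56 and 3.87 normalised counts per library, so no fold is given and a difference was not detectable at this depth. The pooled log2 difference of -0.13 was -0.76 in numbers 1 to 3 and 0.50 in numbers 4 to 6. It turned to 0.01 without wild type 1, to 0.28 without wild type 2 and to 0.06 without knock-out 2 or without knock-out 5. Osmr counts therefore gave no check of the genotype labels. Osmr lies on chromosome 15 from 6813577 to 6874969.

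At the level of single genes, Nnt rose in the Osmr knock-out, and Rita1 and Rhd fell. Nnt, which encodes the mitochondrial transhydrogenase that makes NADPH, went from a normalised count of 270 ± 56.1 in wild type (SD, n = 6) to 952 ± 308 in the knock-out (SD, n = 5). This is 3.44-fold higher, with a log2 fold change of 1.78, a standard error of 0.263 and an adjusted p of 0.0373, and every knock-out library lay above every wild-type library. Rita1, which encodes a tubulin-binding regulator of Notch signalling, had 371 reads in wild type and 1 read in the knock-out (adjusted p 0.0373). Its ratio of wild type to knock-out, corrected for library size, was 227 with a 95% counting interval of 40.5 to 8993. Rhd, which encodes an erythroid membrane protein, had 273 ± 197 in wild type (SD, n = 6) and 8.75 ± 17.3 in the knock-out (SD, n = 5), with a log2 fold change of -6.05, a standard error of 0.938 and an adjusted p of 0.0454.

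The 3 genes differed in the same direction within each number set. Nnt had a log2 fold change of 2.22 in numbers 1 to 3 and 1.23 in numbers 4 to 6. Rhd had -6.58 and -5.75. Rita1 means were 42.8 in wild type and 0 in the knock-out in numbers 1 to 3, and 58.6 and 0.488 in numbers 4 to 6. Nnt lies on chromosome 13 from 119335448 to 119408997, Rita1 on chromosome 5 from 120594305 to 120612589 and Rhd on chromosome 4 from 134864536 to 134896172. GENCODE M21 holds overlapping gene models named Nnt at its position, and which of them the reads were counted on is not given in the sources used here.

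These calls of 1 gene higher and 2 lower were few beside the 2401 genes at an unadjusted p under 0.05, where 667.9 would be expected by chance. They varied with the libraries and the tool: limma called 34 genes higher and 91 lower without wild type 6. It called 0 in either direction without wild type 2, 3, 4 or 5 or without knock-out 2, where 1877, 2436, 2016, 2031 and 2189 genes had an unadjusted p under 0.05. Counts of genes lower were 0 without wild type 1, 4 without knock-out 1, 1 without knock-out 3, 9 without knock-out 5 and 4 without knock-out 6, and counts of genes higher were 0 without knock-out 1 or knock-out 3. On the recovered reads edgeR called 1 higher and 1 lower, and DESeq2 called 238 higher and 436 lower. With the number sets as a covariate, chosen after the data were seen, limma called 133 genes higher and 204 lower. Within numbers 1 to 3 or numbers 4 to 6 alone it called 0, with 2933 and 1384 genes at an unadjusted p under 0.05. Limma also called 0 in either direction with no filter, with the stricter filter and with a replicate block.

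Other genes separated the genotypes without passing the threshold. Afp, a fetal serum protein gene, had 593 ± 187 in wild type (SD, n = 6) and 1530 ± 346 in the knock-out (SD, n = 5). Zmym2, a zinc finger gene, had 762 ± 177 and 1757 ± 381, and Vldlr, a lipoprotein receptor gene, had 399 ± 99.1 and 1247 ± 569. Sigirr, which encodes a negative regulator of interleukin-1 and Toll-like receptor signalling, had 333 ± 70.7 and 86.4 ± 40.5. Tbcc, a tubulin folding cofactor, had 641 ± 182 and 144 ± 73.1, Alad, a heme synthesis enzyme, had 1451 ± 486 and 304 ± 200, and the long non-coding RNA 2810414N06Rik had 109 ± 68.0 and 6.27 ± 9.75. The adjusted p of these 7 genes was 0.0640. Among all tested genes, 336 had no overlap between the genotypes, 146 higher and 190 lower in the knock-out, where chance would give 57.8, or 0.433% of genes.

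**Figure D2:**
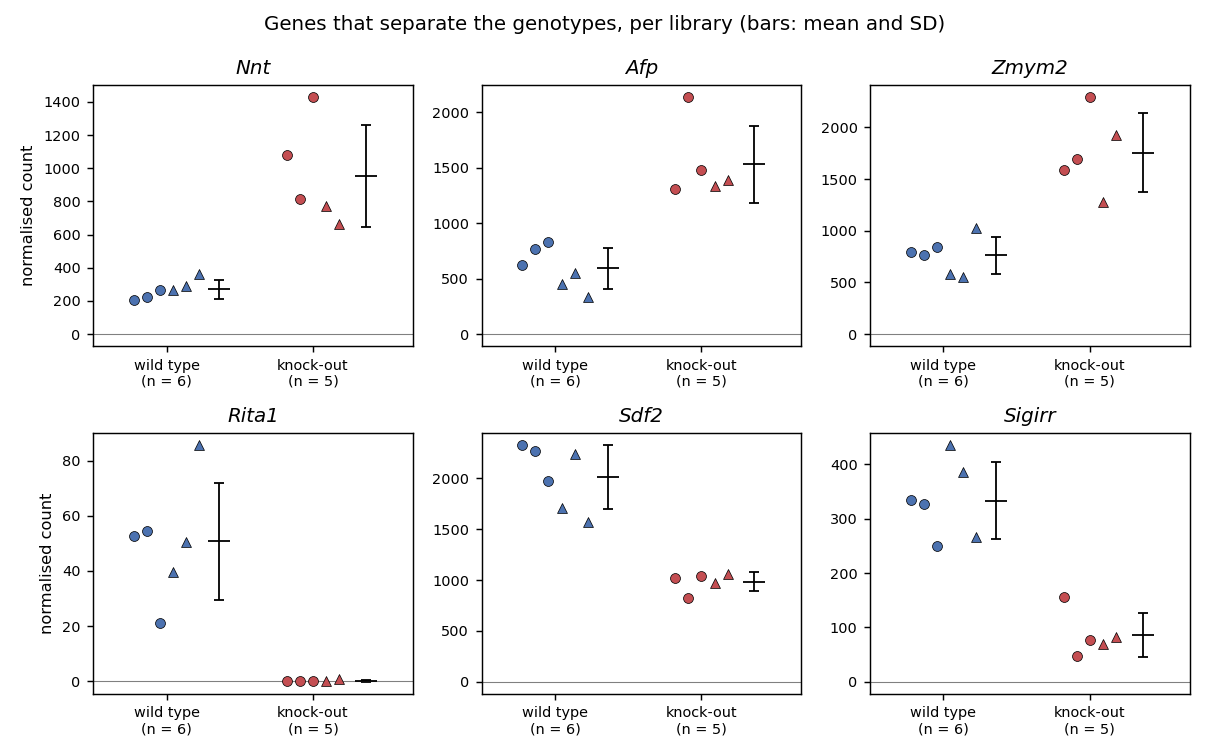
Normalised counts per library of Nnt, Afp, Zmym2, Rita1, Sdf2 and Sigirr, with points for libraries (circles for numbers 1 to 3, triangles for 4 to 6) and bars for mean and SD. The lowest knock-out value of Nnt was 665 and the highest wild-type value 365; Rita1 had at most 0.976 in the knock-out and at least 21.2 in wild type.

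The authors' deposited table held more genes. At an adjusted p under 0.05 from DESeq2, the authors' deposited table listed 615 of 13802 genes, 230 higher and 385 lower in the knock-out. Those of lowest adjusted p that were lower in the authors' deposited table were Rita1, at a log2 fold change of -3.70 and an adjusted p of 2.8e-12, then Sdf2 at -1.0, Sigirr at -1.75, Creb3l3 at -2.80 and Mtch1 at -1.09. Those higher in the authors' deposited table were Nnt, at 1.70 and an adjusted p of 8.0e-09, then Micu3 at 1.15, the platelet and endothelial selectin gene Selp at 2.27, RP23-204I16.3 at 2.30 and Zmym2 at 1.14. Creb3l3, a membrane-bound transcription factor gene on chromosome 10, had 406 reads in wild type and 0 in the knock-out, at least 82.8-fold lower against a floor of 3 reads over the group. DESeq2 with a beta prior on the recovered reads gave the same 615 genes as the authors' deposited table. Of the 603 that limma tested, 603 had the same sign and 602 had an unadjusted p under 0.05. On simulated data this DESeq2 setting made 23 false calls among 95. That simulation changed 100 genes 2-fold and 100 genes 4-fold among 13358. The number of changed genes in the real data is unknown, so this share cannot be carried over to the 615 genes.

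Genes of the red cell lineage were lower together in the knock-out. Of 26 tested members of the erythroid list, 24 lay below 0 and 2 above, with a median log2 fold change of -1.62 (camera adjusted p 8.2e-10, and adjusted p 0.203 with an estimated correlation). Rhd fell over all genes tested, and 25 members did not pass. Adjusted over the list alone, 18 fell and 1 rose, and 19 and 1 with the number sets as a covariate. Blvrb, a biliverdin reductase gene, had 2224 ± 1100 in wild type (SD, n = 6) and 651 ± 313 in the knock-out (SD, n = 5), and Tspo2, an erythroid membrane transporter gene, had 141 ± 108 and 10.9 ± 22.3. Chosen after their values were seen, the carbonic anhydrase genes Car1 and Car2 had log2 fold changes of -2.49 and -1.09 and the erythroid transcription factor gene Klf1 had -4.17, with adjusted p of 0.113, 0.129 and 0.0801. Car1 had -3.66 in numbers 1 to 3 and -1.35 in numbers 4 to 6. The adult globin Hbb-bt went the other way, with 316 ± 208 in wild type (SD, n = 6) and 1162 ± 390 in the knock-out (SD, n = 5), an adjusted p of 0.0640 and sequence close to that of Hbb-bs, so its reads are uncertain.

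The mean log2 level of the erythroid list was lower in all 5 knock-out libraries than in any wild-type library, by -1.84, with an exact permutation p of 0.0022, the smallest possible, and 0.0433 adjusted over the 40 lists. Within the number sets the adjusted p was 0.1. The summed counts of the list had an exact permutation p of 0.0130, and 0.0595 adjusted over 11 lists. The median was -1.99 in numbers 1 to 3 and -1.0 in numbers 4 to 6. Wild-type libraries 1 to 3 had summed erythroid normalised counts of 64532, 61981 and 72837, wild types 4 to 6 had 23718, 25132 and 25822, and the knock-outs had 15673 to 22621. Cells with the mature erythroid marker TER119 were removed by the sort.

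**Figure D3:**
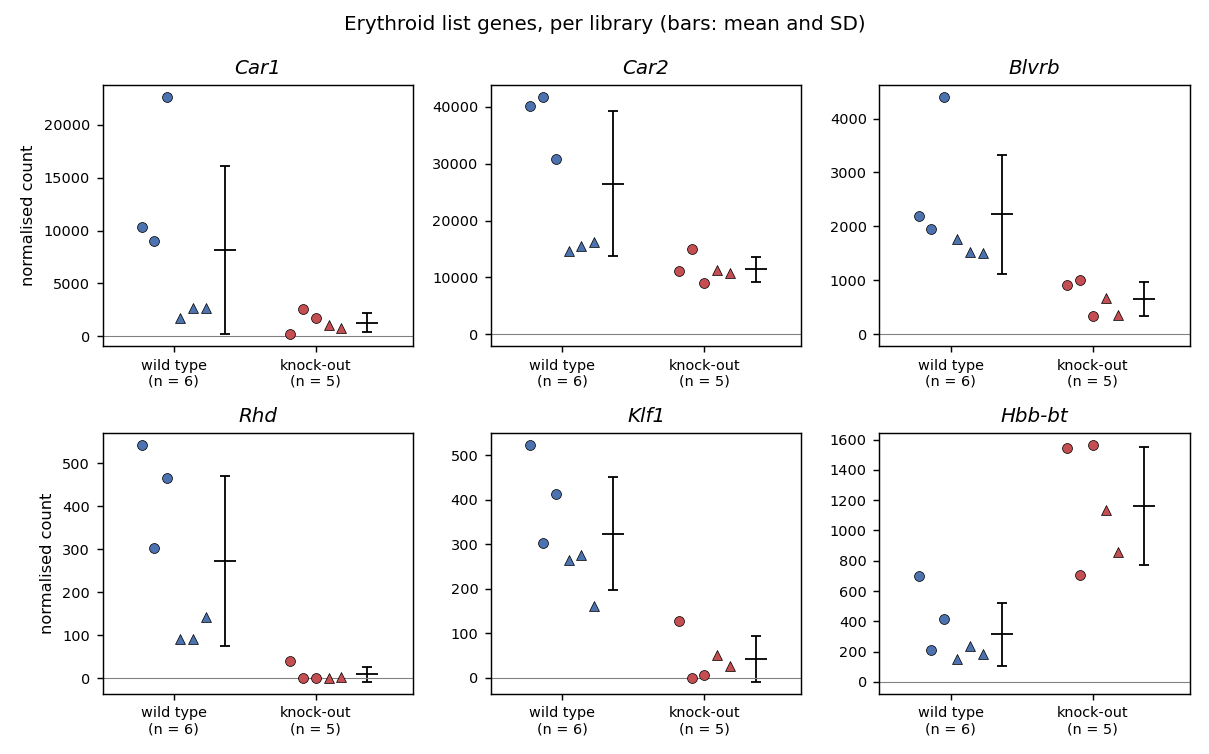
Normalised counts per library of Car1, Car2, Blvrb, Rhd, Klf1 and Hbb-bt from the erythroid list, with points for libraries (circles for numbers 1 to 3, triangles for 4 to 6) and bars for mean and SD. Rhd had at least 90.8 in wild type and at most 39.6 in the knock-out, while Hbb-bt had at most 697 in wild type and at least 707 in the knock-out.

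Mitotic genes were also lower. In the G2/M phase list 45 of 54 tested members lay below 0 and 9 above, with a median log2 fold change of -0.65 (camera adjusted p 2.16e-05, and adjusted p 0.660 with an estimated correlation). Over all genes tested 0 passed in limma, and adjusted over the list alone 6 fell. In the fit with the number sets 3 fell over all genes and 11 over the list alone. The centromere gene Cenpa had 1691 ± 743 in wild type (SD, n = 6) and 639 ± 231 in the knock-out (SD, n = 5). Ccnb2, a mitotic cyclin gene, had 1840 ± 1177 and 462 ± 305, with log2 fold changes of -3.15 in numbers 1 to 3 and -0.51 in numbers 4 to 6. Hmmr had 643 ± 209 and 251 ± 129, and the kinetochore gene Nuf2 had 484 ± 294 and 123 ± 58.5. The median was -0.83 in numbers 1 to 3 and -0.28 in numbers 4 to 6, where the list did not pass (adjusted p 0.192). The difference between the sets had an adjusted p of 0.0098, and 0.666 with an estimated correlation.

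S phase and quiescence genes showed no shift by the list test. In the S phase list 26 of 48 members lay below 0 and 22 above, with a median of -0.04 (adjusted p 0.851, and 0.870 with an estimated correlation), and adjusted over the list alone 0 passed, while 3 fell with the number sets as a covariate. Its members of lowest p were the replication genes Rfc2, Mcm10 and Pold3, at -1.12, -2.43 and -1.20. In the list of quiescence regulators 16 of 28 lay below 0 and 12 above, with a median of -0.12 and a mean of -0.44 (adjusted p 0.456), and adjusted over the list alone 0 passed. Its lowest p belonged to Rbl1, a retinoblastoma family gene, at 0.70, and to the cyclin-dependent kinase inhibitor genes Cdkn2c and Cdkn2d, at -1.50 and -1.31. By the exact permutation test of list means, added after the data were seen, the quiescence list was lower in all 5 knock-out libraries, with an adjusted p of 0.0433, and of 0.1 within the number sets.

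Ribosomal protein and respiration genes were higher as lists. The list of ribosome biogenesis genes and MYC targets went the other way, with 36 of 56 members below 0 and a median of -0.30. Its camera adjusted p was 0.117, and 0.732 with an estimated correlation. With the number sets as a covariate it was 0.0384, and 0.701 with an estimated correlation. Of 79 ribosomal protein genes, 60 lay above 0 and 19 below, with a median log2 fold change of 0.39 (camera adjusted p 1.47e-07, and adjusted p 0.732 with an estimated correlation). Over all genes tested and adjusted over the list alone 0 of them passed. Over the list alone 33 rose and 2 fell with the number sets as a covariate, and 8 rose over all genes. Rps15a had 7013 ± 2996 in wild type (SD, n = 6) and 13669 ± 3488 in the knock-out (SD, n = 5), and Rpl39, Rpl30 and Rpl35a had log2 fold changes of 1.45, 0.83 and 0.95. The median was 0.59 in numbers 1 to 3 and 0.06 in numbers 4 to 6, where the list did not pass (adjusted p 0.620). The difference between the sets had an adjusted p of 4.46e-13, and 0.666 with an estimated correlation. Ribosomal protein genes have many near-identical pseudogenes, so reads of single members are uncertain.

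All 12 tested genes of the mitochondrial genome lay above 0, with a median of 0.96 (camera adjusted p 1.56e-05, and adjusted p 0.660 with an estimated correlation). Adjusted over the list alone 4 rose, and over all genes tested 0 did. These counts were 7 and 2 with the number sets as a covariate. The complex I subunit genes mt-Nd2, mt-Nd4, mt-Nd1 and mt-Nd6 had 1.31, 0.93, 1.18 and 0.93. Members differed widely in level. Chosen after their values were seen, mt-Co2 and mt-Co3 had mean normalised counts of 55.0 and 68.0 in wild type, beside 121552 for mt-Co1. Counts of single members are therefore uncertain. The medians were 1.00 in numbers 1 to 3 and 0.89 in numbers 4 to 6. With gene length and GC trends removed the median was 0.41 (adjusted p 0.0315). Mitochondrial reads made up 5.88% ± 1.91 in wild type (SD, n = 6) and 7.61% ± 0.483 in the knock-out (SD, n = 5), with an exact permutation p of 0.0887.

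The oxidative phosphorylation list, whose 76 tested genes are nuclear, had 51 members above 0 and 25 below, with a median of 0.39 (camera adjusted p 0.0011, and adjusted p 0.732 with an estimated correlation). Adjusted over the list alone 6 rose and 6 fell, so the members that moved went both ways, and over all genes tested 0 passed. The covariate for the number sets gave 32 higher and 13 lower over the list alone, and 9 and 4 over all genes. The members of lowest p were mostly lower: Uqcrc1, of complex III, had 3148 ± 1754 in wild type (SD, n = 6) and 744 ± 445 in the knock-out (SD, n = 5), Ndufv1 of complex I had a log2 fold change of -1.37 and Atp5d of the ATP synthase had -0.88. Cox7b, of cytochrome oxidase, had 1.23. The medians were 0.34 in numbers 1 to 3 and 0.36 in numbers 4 to 6. With gene length and GC trends removed the median was 0.52 (camera adjusted p 7.23e-08). Lengths came from annotation, so a trend of the members with expressed transcript length was not tested. The list did not pass without knock-out 2 (adjusted p 0.0854) or with quantile scaling (adjusted p 0.0769).

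Fatty acid oxidation and antigen presentation lists were lower. In the fatty acid oxidation list 21 of 22 tested members lay below 0 and 1 above, with a median of -0.61 (camera adjusted p 3.63e-04, and adjusted p 0.660 with an estimated correlation). Over all genes tested and adjusted over the list alone 0 passed. The fit with the number sets gave 1 lower over all genes and 11 over the list alone. The acyl-CoA dehydrogenase gene Acads had -2.73, the thiolase gene Acaa2 had -1.17, and Eci1 and Hadh had -0.84 and -0.88. The medians were -0.90 in numbers 1 to 3 and -0.46 in numbers 4 to 6.

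In the antigen presentation list 18 of 22 members lay below 0 and 4 above, with a median of -0.54 (camera adjusted p 0.0153, and adjusted p 0.660 with an estimated correlation). Adjusted over the list alone 3 fell and 1 rose, and over all genes tested 0 passed. With the number sets as a covariate 11 fell and 3 rose over the list alone, and 2 fell and 1 rose over all genes. The class II genes H2-Ab1 and Cd74 had 1207 ± 783 and 3072 ± 1967 in wild type (SD, n = 6) and 320 ± 142 and 1063 ± 266 in the knock-out (SD, n = 5). Psmb10, an immunoproteasome gene, had a log2 fold change of -0.91, and Nlrc5, a class I transactivator gene, had 1.02. Dendritic cell and macrophage markers, which share both class II genes with this list, were also lower, with summed normalised counts of 10224 ± 3533 in wild type (SD, n = 6) and 6594 ± 687 in the knock-out (SD, n = 5). Their exact permutation p, from a test chosen after the data were seen, was 0.0130, and 0.0595 adjusted over 11 lists. Most of this fall in summed counts is that of H2-Ab1 and Cd74, and the marker list did not pass the camera test (adjusted p 0.145, and 0.660 with an estimated correlation). The medians of the antigen presentation list were -0.49 in numbers 1 to 3 and -0.32 in numbers 4 to 6, where the list did not pass (adjusted p 0.0769), and the difference between the sets had an adjusted p of 0.604. It also did not pass with gene length and GC trends removed, where the median was -0.10 (adjusted p 0.708), without the variance trend (0.0571) or with 1 surrogate variable (0.0508).

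**Figure D4:**
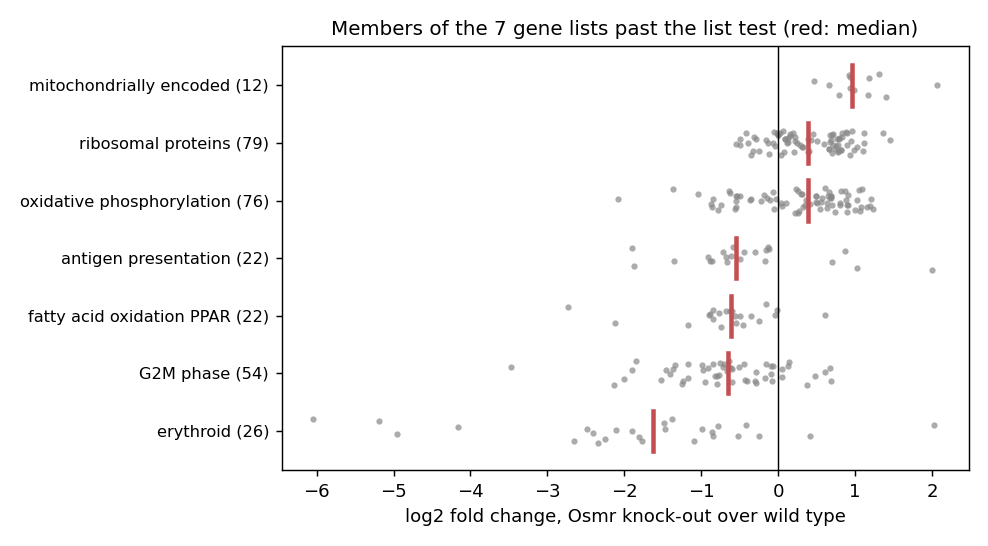
Log2 fold change, knock-out over wild type, of each tested member (grey points) of the 7 gene lists past the camera test, with the median in red and the number of members in brackets. Medians run from -1.62 in the erythroid list to 0.96 in the mitochondrially encoded list.

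The count of 7 lists among 40 was not unusual for these libraries, since 25 of 100 splits, the real one included, gave as many. With an estimated correlation camera passed 0 lists, where 2 lists had an unadjusted p under 0.05.

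Genes tied to the receptor pathway and to stem cell identity showed no shift in 1 direction as lists. In limma's fry test for changes in either direction they had adjusted p of 6.19e-04 and 5.25e-04. That test passed 28 of the 40 lists, so it sets few of them apart. In the OSM, gp130 and JAK-STAT list 18 of 32 members lay above 0 and 14 below (adjusted p 0.536, and 0.850 with an estimated correlation), and adjusted over the list alone 1 fell. Its members of lowest p were the interleukin-11 receptor gene Il11ra1 at -1.91, the adaptor gene Grb2 at -0.90 and the feedback inhibitor gene Socs2 at 0.92, with adjusted p over all genes of 0.0896, 0.131 and 0.134. In the long-term stem cell identity list 23 of 44 lay below 0 and 21 above (adjusted p 0.951), and adjusted over the list alone 1 fell. The covariate for the number sets gave 5 higher and 7 lower over the list alone, so members that moved went both ways. The lymphotoxin gene Ltb had 3855 ± 1216 in wild type (SD, n = 6) and 1297 ± 626 in the knock-out (SD, n = 5), the transcriptional repressor gene Gfi1b had a log2 fold change of -1.39 and the tetraspanin gene Cd82 had -2.45. In the adhesion and homing list 34 of 52 lay below 0 and 18 above (adjusted p 0.456), and adjusted over the list alone 1 rose. The selectin ligand gene Selplg had a log2 fold change of -0.95.

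Genes next to Osmr on chromosome 15 also showed no shift in 1 direction as a list. Fry in either direction gave the flanking list an adjusted p of 0.0013, again among the 28 lists that passed. Of 19 tested flanking genes 12 lay above 0 and 7 below (adjusted p 0.914), and adjusted over the list alone 2 fell, while 1 rose and 2 fell with the number sets as a covariate. Fbxo4, Fyb and Rpl37 had -1.34, -0.93 and 0.98. Fbxo4 and Fyb were lower in every knock-out library than in any wild-type library, as were 190 of all tested genes. Their adjusted p from DESeq2 in the authors' deposited table was 0.0276 and 0.0161. In the list of genes known to differ between C57BL/6 substrains or from the 129 strain, Nnt rose and 6 of 7 did not pass (adjusted p 0.536). Casp4 and Ide had 0.48 and -0.39.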

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

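Of the tests below, the globin and megakaryocyte tests of the erythroid genes, the tests of chromosome 15 and of the number sets for Nnt, Hbb-bt and Rita1, and for the ribosomal protein and mitochondrial genes the tests with the number sets as a covariate and of mitochondrial gene length and GC content, were chosen only after the result was seen; the number sets themselves were also defined from the data.

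Single libraries stood far from the rest of their group in 19 of 153 groups examined, where chance gives about 5%. Wild type 1 had 22.1 M reads against 9.89 to 13.6 in the other wild types. Wild type 2 had an Osmr normalised count of 6.72 against 0 to 2.08. Wild type 3 was high in Rpl39 (5623), Cox7b (9307), mt-Nd2 (23165), mt-Nd1 (99000), mt-Nd6 (23206) and Blvrb (4404). Wild type 6 had a summed lymphoid priming count of 8727 against 4547 to 5844. Knock-out 1 was high in Rhd (39.6) and RP23-204I16.3 (168) and low in summed B cell markers (759). Knock-out 2 had 2138 for Afp against 1312 to 1476 in the other knock-outs. Knock-out 3 had summed counts of 40389 for granulocyte and monocyte markers, against 16382 to 20436, and of 23483 for megakaryocyte markers. Its S100a8, S100a9 and Camp counts were 10780, 7277 and 5197. Knock-out 6 was high in 2810414N06Rik (23.4), Tspo2 (50.7) and Ide (2085), and held the single Rita1 read of its group (0.976).

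Erythroid genes were lower in the knock-out, and cells richer in red cell transcripts in the wild-type sorts are a candidate source. As a test for haemoglobin-rich erythroid cells, mean summed globin counts went from 654 in wild type to 1264 in the knock-out. Car1 plus Car2 went from 34662 to 12700. The ratio of the falls was -0.0278, between -0.0426 and -0.0210 without any single library. The rise came from Hbb-bt, whose reads are uncertain. The other 3 globins fell, from 338 to 102 summed. Without Hbb-bt the ratio was 0.0107, between 0.0065 and 0.0145 without any single library, where such cells would need at least 1. Globin genes have close copies, so reads shared between copies may be missing from these sums. A ratio below 1 therefore cannot decide, and haemoglobin-rich erythroid cells stay open. The number sets are argued against as the whole cause, since the list mean was lower within both sets. The exact permutation p was 0.005, the smallest that 200 splits can give, and 0.1 adjusted over the 40 lists. With the sets as a covariate the list had a median of -1.73 (camera adjusted p 1.07e-09, and 0.0744 with an estimated correlation). The sets are nearly balanced over the genotypes, so that fit could move the median only a little and adds no support. Megakaryocyte-biased progenitors stay open: the megakaryocyte list had a median of -0.20, above -0.81, with a standard error over its member genes of 0.219. That error is a spread over genes and not over mice. The list's knock-out level of 19833 summed counts is also high enough beside the erythroid fall of 27737 to hide a small share. An effect of Osmr loss on the cells inside the gate stays open and untested.

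Nnt and Rita1 passed the threshold between the genotypes, and Hbb-bt separated them without passing (limma adjusted p 0.0640), with uncertain reads. The strain background of the knock-out may be a source, since C57BL/6 substrains are known to differ at Nnt. A segment carried along with Osmr is argued against for these genes, since 0 of the 3 lie on chromosome 15. The number sets are argued against as well, since with the sets as a covariate, which took the called genes to 337, the log2 fold changes of Nnt, Hbb-bt and Rita1 were 1.78, 1.95 and -5.33, with a highest adjusted p of 0.0329. The sets are nearly balanced over the genotypes, so that fit could move these values little, but each gene also kept its direction within both sets. Strain differences at several loci stay open: the 100 genes of lowest p held 12 neighbour pairs within 1 Mb, where random draws had a median of 7, with a permutation p of 0.0538. An effect of Osmr loss itself was not tested apart from strain, because every knock-out mouse could share both.

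Ribosomal protein and mitochondrial genes were higher as lists. Gene length and GC content were taken from the longest annotated transcript of each gene. With trends in these annotated values removed, the ribosomal protein list had a median of 0.58 and a camera adjusted p of 1.63e-17. Trends in the annotated values are therefore argued against as its whole cause. The longest transcript need not be the expressed one, so trends with expressed transcript length stay open. The highest adjusted p over the list's alternatives was 0.732, with an estimated correlation. The number sets are nearly balanced over the genotypes, so a shift between them common to both genotypes could move these medians only a little. It is the design, rather than a fit, that argues against such a shift as the whole cause. With the sets as a covariate the medians were 0.35 for ribosomal protein and 0.91 for mitochondrial genes, beside 0.39 and 0.96 without it. The higher camera adjusted p was 2.37e-06. With an estimated correlation neither list passed, with the covariate (adjusted p 0.728 and 0.701) or without it (0.732 and 0.660). Whether the ribosomal protein difference is the same in both sets stays open, with mean differences of 0.59 in numbers 1 to 3 and 0.05 in numbers 4 to 6: the difference between the sets had an adjusted p of 4.46e-13, but of 0.666 with an estimated correlation. The exact permutation p of the list mean was 0.105 within the sets and 0.0952 without them. Length and GC trends stay open for the mitochondrial genes, whose median went from 0.96 to 0.41 (adjusted p 0.0315) with the trends removed. An effect of Osmr loss stays open and untested.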

How the results depend on the processing

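The settings with the number sets, with the length and GC correction, without wild type 1 and knock-out 3, with a beta prior and with exact tests of list means were chosen only after the data were seen. All 63 tested genes chosen by the naming rule kept their direction under every alternative run. The 7 lists kept their direction under every alternative run and their side of the threshold in 230 of their repeats. They did not pass in 22, most of them with an estimated correlation, and the values of the others stand beside their lists in the report.

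The calls of 1 gene higher and 2 lower moved most. Genes higher and lower were 13 and 42 with a pseudocount of 10, 14 and 42 with quantile scaling, 17 and 49 with the authors' variance stabilised values, 18 and 51 with their regularised log values, and 17 and 42 with edgeR without a filter. DESeq2 gave 238 and 436, and 230 and 385 with a beta prior. With the number sets as a covariate limma gave 133 and 204, and edgeR gave 64 and 133. Limma gave 0 and 0 with no filter, with the stricter filter, with a replicate block, and within numbers 1 to 3 or 4 to 6 alone, at 2779, 2122, 2418, 2933 and 1384 genes with an unadjusted p under 0.05. It gave 0 and 4 without the trend, 1 and 0 with 1 surrogate variable, 0 and 1 without wild type 1 and knock-out 3, and 2 and 1 with the length and GC correction. Array weights, a pseudocount of 0.5 and edgeR each gave 1 lower. Leaving out single libraries gave 0 to 34 higher and 0 to 91 lower, with the upper ends without wild type 6. The cause was not tested, except that fewer libraries enter the number sets and leave-outs and that the filters change the number of genes tested.

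The count of 7 lists became 0 with an estimated correlation, with or without the number sets, and 0 with exact tests of list means within the number sets. It was 1 with fry in 1 direction, 28 with fry in either direction, and 2 with exact tests of list means, both as they stand and less the mean of all genes. Under the other alternatives it ran from 6 to 10. The Osmr difference of -0.13 ran from -0.33 to 0.28 over single left-out libraries, turning positive without wild type 1 (0.01), wild type 2 (0.28), knock-out 2 (0.06) or knock-out 5 (0.06), and was 0.50 in numbers 4 to 6. With 13 and 4 reads, depth limits any statement on Osmr.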

Other observations

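The exact tests of summed markers and the number sets below were chosen only after the data were seen; the splits of the libraries were planned, except those with the number sets as a covariate.

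Other gene groups and cell types went both ways, and none of the lists here passed the camera test in the main fit. In the glycolysis list 18 of 24 members lay below 0, with a median of -0.51 (adjusted p 0.0533, and 0.660 with an estimated correlation), and adjusted over the list alone 3 fell and 1 rose. It passed with the number sets as a covariate (adjusted p 0.0378, and 0.701 with an estimated correlation) and in numbers 1 to 3 (0.0116) but not in numbers 4 to 6 (0.801), a difference between the sets with an adjusted p of 0.0480, and 0.666 with an estimated correlation. Lymphoid priming genes had a summed normalised count of 5871 ± 1508 in wild type (SD, n = 6) and 8219 ± 934 in the knock-out (SD, n = 5), with an exact permutation p of 0.0173 and 0.0595 adjusted over 11 lists. Its list had 7 of 12 members above 0 (adjusted p 0.147), and adjusted over the list alone 2 rose. Megakaryocyte and granulocyte lists had adjusted p of 0.532 and 0.727, and markers of B cells, T and NK cells, mast cells, endothelium and stroma had 0.851, 0.302, 0.721, 0.959 and 0.6249. The interferon response list had 30 of 54 members above 0 (adjusted p 0.255), with medians of -0.17 in numbers 1 to 3 (adjusted p 0.663) and 0.43 in numbers 4 to 6, where it passed (adjusted p 0.0012), a difference with an adjusted p of 0.0074, and 0.666 with an estimated correlation.

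Chosen after their values were seen, the heat shock gene Hspa1b had a normalised count of 3.52 ± 5.48 in wild type (SD, n = 6) and 84.2 ± 78.9 in the knock-out (SD, n = 5), with an adjusted p of 0.0706, and Hspa1a is a near-identical copy, so its reads are uncertain. Wfdc17 had 727 ± 549 and 2997 ± 1560, with an adjusted p of 0.0801. On chromosome 10, Wdr18, Pcsk4, Creb3l3 and Tbxa2r lie in a row among the 100 genes of lowest p, and all were lower in the knock-out means. The Y-linked gene Ddx3y had 1402 ± 605 and 1931 ± 406, and Xist had at most 90.8 in any library.

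Chance was examined by splitting the 11 libraries anew into groups of 6 and 5, for 100 of 462 possible splits. For genes higher, 2 of 100 splits, the real one included, gave as many as the real 1, and the highest other gave 1. For genes lower, 1 of 100, the real split itself, gave as many as the real 2, and the highest other gave 1. Few splits gave as many, but counts this small with 100 of 462 splits drawn do not exclude chance. For lists, 25 of 100 gave as many as the real 7, and the highest other gave 12, so chance is not excluded. With the number sets as a covariate, 2 of 100 splits drawn within the sets, of 200 possible, gave as many as the real 337 genes, the real one included. The highest other gave 1007 and set wild types 1 to 5 against wild type 6 with the knock-outs, which points to a structure of the samples. Chance is not excluded, because another split gave more genes and the number sets were defined from these data. Wild type 6 had 365 for Nnt, 85.8 for Rita1 and 138 for Creb3l3, on the wild-type side of each. A split along the number sets with genotype ignored gave 469 genes, 185 higher and 284 lower in numbers 4 to 6.

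The genotype difference was also tested for a difference between the number sets. In limma 0 genes passed, with 1316 at an unadjusted p under 0.05. Of the lists, 9 passed with the preset correlation and 0 with an estimated one. The erythroid list had an adjusted p of 0.0149 and, with an estimated correlation, of 0.447.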
